A study of Homo sapiens with 4 samples.

How the data were processed

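The series compared saracatinib with no treatment in EGI-1, an established human biliary tract carcinoma cell line. Saracatinib is a small-molecule inhibitor of Src family and Abl kinases. Cultured cells received 10 µM for 24 hours, and EGI-1 xenografts received 25 mg/kg per day for 21 days, per the labels' protocols. Total RNA was extracted, amplified once to amino allyl antisense RNA and coupled to Cy3 or Cy5, per the labels' protocols.

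There were 4 arrays, 2 per system. On replicate 1 of each system the treated RNA carried Cy5 and the untreated RNA Cy3, and on replicate 2 the dyes were exchanged, as the channel labels give. The labels name the arrays of a pair as a normal and a swapped labelling. They were read as a technical dye swap of 1 treated and 1 untreated RNA, and were averaged into 1 value per gene and system. On this reading the spread between the arrays of a pair is technical, and nothing in the data measures the spread between separate cultures or animals within a system.

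The spot files hold the intensity of each spot in 2 colours as mean signal and median local background, written by Agilent Feature Extraction 10.7.3.1, per the file headers. They also hold a log10 ratio of red (Cy5) over green (Cy3) after the scanner software's own background subtraction and dye normalization, per the file headers. The probe positions are on hg19 (GRCh37), per the file headers. All 4 arrays lay on 1 slide with 1 scan time, per the file headers, so a slide or scan effect could not be fitted. The authors' series matrix holds 1 value per probe and array. Set against the scanner log ratios, these deposited values were on a log2 scale (slopes 0.957 to 0.962 on bright probes), ran treated over untreated on all 4 arrays, and had medians of 0.07, -0.06, 0.03 and -0.08 for xenografts 1 and 2 and cultured cells 1 and 2. Their centring and background correction are not given in the sources used here. The submitters' processing notes name limma.

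The analysis started from the spot intensities. Background was corrected with limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table) by normexp with an offset of 50. Each array was normalized by loess, with control spots given weight 0. Each array held 58717 spots of 42405 probes besides controls. Spots with outlier flags (622 to 782 per array) were left out, no spot was saturated, and spots of a probe were averaged. The 999 probes spotted 10 times had a median SD between spots of 0.0939 to 0.0977 log2. Ratios were turned to treated over untreated on every array. For bounds and untreated levels, channel values were computed after loess and Aquantile normalization between arrays.

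Probes were named through RefSeq's table of GRCh38.p14, used for names and not for coordinates. Of the probes, 24910 matched by accession, 216 by another accession in the file, 1718 by symbol and 536 by an older symbol, and 15025 kept the file's name. This gave 34015 genes, 20171 of them named through RefSeq. Where a gene had several probes, the brightest over all arrays stood for it. A gene was tested in a system where 1 channel was well above background on both arrays, which held for 18284 genes in cultured cells and 21107 in xenografts.

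With 1 RNA pair per system there are no residual degrees of freedom, so no p-value was computed within a system. A size rule was used: a mean log2 ratio of at least 1 in size (2-fold), with at least 0.5 in that direction on each array. The mean of the 2 arrays left unturned, in which treatment cancels and dye bias stays, was put through the same rule as a technical background. Values after ± are the SD of the 2 dye orientations. That SD includes dye bias, which cancels in the mean where it is equal on both arrays, so it is not the error of the mean. Across the 2 systems, the only independent RNA pairs, limma (lmFit and eBayes, 2 averaged columns, intercept, two-sided, Benjamini-Hochberg adjusted p under 0.05) tested for genes changed alike.

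There were 33 gene lists fixed before the data were examined, with 601 entries. A list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, drawn from protein-coding genes and matched on signal in 10 bins. It was called shifted below percentile 2.5 or above 97.5. This describes these RNA pairs and is no test between conditions.

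The genes named were also set by rule before the data were examined, though not every gene the rule picked is named. They were the 12 highest and 12 lowest per system among genes past the size rule and measured in both channels, and every measured Src family kinase. Rankings skipped genes not named through RefSeq, LOC and open-reading-frame names, XIST and genes of chromosome Y. Up to 4 members of each list past the rule, or its 2 largest if none passed, were added. So were up to 8 genes past the rule in both systems each way or in opposite directions, and up to 3 per direction that were measured in 1 group alone. Such genes have a bound: the bright group's mean against the higher of the dim probe's own level and the lowest signal among probes well above background.

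The steps were tested on simulated data made from these arrays. Planted log2 changes of 1.5 and 2.5 were recovered by the size rule for 100% and 100% of 100 genes each in cultured cells (18284 genes) and 99% and 100% in xenografts (21107 genes), with 0 other genes called. The limma test over both systems (18069 genes) recovered 98% and 100%, with 4 other genes called. The planted changes were equal in both systems with Gaussian noise, so this recovery need not hold for these data. For the size rule, simulated dye effects cancelled in the mean and the noise was small against the threshold. The 0 other calls therefore do not measure false calls, and no spread between cultures or animals was simulated. The real unturned arrays gave 10 genes in cultured cells and 15 in xenografts. UBD, at 2.001 in cultured cells and 2.20 in xenografts, was not called by limma, whose smallest adjusted p was 0.328. A list of 20 genes shifted by 0.5 reached percentile 100 in each system.

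The alternatives tried were Agilent's own log ratio, no background subtraction, an offset of 0, median centring, the authors' matrix, other filters on dim probes, all probes of a gene, thresholds of 1.5-fold and 3-fold, no condition on single arrays, another prior in limma, unmatched random lists, limma on the 4 arrays as separate replicates, and each array left out in turn. With 1 array of a pair left out, dye bias no longer cancels, and the size rule becomes 1 log2 on the remaining array alone. Such settings therefore do not measure dependence on a replicate alone. The number of arrays limits the precision of every value.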

Results

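Gene expression was measured on 4 two-colour arrays to ask how the transcriptome of the human biliary tract carcinoma line EGI-1 differed after saracatinib, an inhibitor of Src family and Abl kinases, in culture and in xenografts. Cultured cells (10 µM, 24 hours) and xenografts (25 mg/kg per day, 21 days) each gave 1 treated and 1 untreated RNA, hybridized together on 2 arrays with exchanged dyes. Between 53.5% and 64.4% of probes were well above background in the red channel and between 45.7% and 58.1% in the green channel. Values are mean log2 ratios of treated over untreated, with the SD of the 2 dye orientations. The labels were read as a technical dye swap with no replicate culture or animal, so this SD is taken as technical. They do not give the number of animals behind a xenograft RNA. Genes are said to have risen or fallen where they passed the size rule: a mean of at least 2-fold, with at least 0.5 log2 in that direction on each array. Probe positions are on hg19.

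In cultured cells after saracatinib, the integrated stress response list had the lowest median of the lists, and 9 of its 16 measured genes fell. Among RefSeq-named genes measured in both groups, SLC7A11, the cystine transporter subunit gene (probe on chromosome 4, 139085433 to 139085492), fell the most, by 2.58 ± 0.05 log2 or 5.98-fold. The serine synthesis gene PSAT1 fell by 2.45 ± 0.05 and asparagine synthetase, ASNS, by 2.40 ± 0.17. The largest rise among such genes was that of ALDH1A1, a retinaldehyde dehydrogenase (chromosome 9, 75516136 to 75516195), at 2.74 ± 0.39 or 6.66-fold. In all, 208 of 18284 tested genes rose and 190 fell. The unturned arrays, which carry dye bias and no treatment effect, gave 10 genes by the same rule.

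Other genes among the 12 lowest such genes in cultured cells were the LIM protein gene FHL1 (-2.38 ± 0.13), STC2 (-2.34 ± 0.93), the focal adhesion gene TNS4 (-2.27 ± 0.12), MIR100HG (-2.23 ± 0.27) and LY6K (-2.15 ± 0.28). They also held the AP-1 subunit gene FOSL1 (-2.09 ± 0.17; chromosome 11, 65660098 to 65660157), ANKRD1 (-1.92 ± 0.30), KLF2 (-1.89 ± 0.19) and the decoy receptor gene TNFRSF6B (-1.88 ± 0.41). Among the 12 highest, BNIP5 rose by 2.43 ± 0.03, RASD1 by 2.17 ± 0.15 and the glutathione peroxidase gene GPX2 by 2.13 ± 0.18. TGFB3 rose by 2.09 ± 0.04, the ubiquitin-like modifier gene UBD by 2.001 ± 0.12, the mucin gene MUC16 by 2.001 ± 0.18 and FCGBP by 1.98 ± 0.05. LDLRAD1 rose by 1.97 ± 0.13, the aldo-keto reductase gene AKR1C1 by 1.95 ± 0.06 and the chemokine gene CXCL10 by 1.93 ± 0.08. COL16A1 rose by 2.16 ± 0.02 on its brightest probe, while its other probe gave 0.14.

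The integrated stress response list, whose genes are targets of ATF4 or its partners, had the lowest median in cultured cells, at -1.21, below all random lists (percentile 0). Of its 16 measured genes 9 fell and 0 rose, with SLC7A11, PSAT1, ASNS and STC2 in front. Output genes of the ERK pathway had a median of -0.76 (percentile 0), and 10 of 23 fell, among them FOSL1, HBEGF (-1.56 ± 0.11), the phosphatase gene DUSP6 (-1.45 ± 0.34) and EMP1 (-1.37 ± 0.06). Of 12 immediate-early genes, KLF2 and EGR1 (-1.63 ± 0.14) fell and the median was -0.30 (percentile 0.40). With the filter on both channels this list was no longer called, at percentile 3.36.

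Cell cycle genes were lower after treatment in culture. All 30 DNA replication and G1/S genes were measured, 14 of them fell and 0 lay above 0, with a median of -0.95 (percentile 0). The ribonucleotide reductase gene RRM2 was at -1.40 ± 0.06, the replication fork gene CDC45 at -1.39 ± 0.12 and the clamp loader genes RFC3 and RFC4 at -1.39 ± 0.12 and -1.20 ± 0.06. Of the 28 mitosis and G2/M genes, 0 lay above 0 and 3 fell, namely TOP2A (-1.14 ± 0.18), CDK1 (-1.07 ± 0.21) and KIF23 (-1.05). Their median was -0.73 (percentile 0).

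Genes of adhesion and of YAP/TEAD output were also lower in treated cells. The YAP/TEAD list had a median of -0.59 (percentile 0), and ANKRD1, TGFB2 (-1.46 ± 0.44) and the receptor kinase gene AXL (-1.39 ± 0.07) fell among 24 measured genes. The list of focal adhesion genes and Src substrates had a median of -0.26 (percentile 0.01), and caveolin 1, CAV1, fell (-1.01 ± 0.12) among 26. Hypoxia and glycolysis genes had a median of -0.41 (percentile 0). The lipase inhibitor gene ANGPTL4 (-1.60 ± 0.04), the lactate dehydrogenase gene LDHA (-1.07 ± 0.16) and PDK1 (-1.02 ± 0.28) fell among 19. Of 9 mesenchymal identity genes, LOXL2 fell (-1.07 ± 0.01, with treated cells above background on 1 of the 2 arrays) and the median was -0.25 (percentile 1.505). That call was lost with the filter on both channels (percentile 14.1) and without cultured cells replicate 2 (percentile 5.25).

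Lipid synthesis, chemokine and interferon genes lay higher in treated cells. All 24 cholesterol synthesis genes lay above 0 with a median of 0.41 (percentile 100), and TM7SF2 rose (1.28 ± 0.24). Of 10 fatty acid synthesis genes, the desaturase gene SCD (1.17 ± 0.05) and ACSS2 (1.09 ± 0.22) rose, and the median was 0.41 (percentile 99.9). With median centring in place of loess both lists had a median of 0.22 (percentiles 100 and 99.8), and 0 genes of either list passed the rule. The NF-kB and chemokine list had a median of 0.41 (percentile 100) over 20 genes, of which CXCL3 (1.30 ± 0.24) and CCL20 (1.16 ± 0.41) rose and IL1A fell (-1.56 ± 0.19). Of 23 interferon response genes, 20 lay above 0 and CXCL10 rose, with a median of 0.34 (percentile 99.99). Lysosome and autophagy genes had a median of 0.25 (percentile 99.8), and WIPI1 rose (1.23 ± 0.02) among 25.

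Of 12 histone genes, H2AC6 rose (1.25 ± 0.10) and H4C3 fell (-1.16 ± 0.43), with a median of 0.41 (percentile 99.97). Epithelial identity genes had a median of 0.25 (percentile 99.6), and the claudin gene CLDN3 rose (1.29 ± 0.21) among 19. That call was lost without cultured cells replicate 1 (percentile 97.3). The 7 aryl hydrocarbon receptor targets had a median of 0.27 (percentile 98.1), and ALDH3A1 rose (1.20 ± 0.29). The call of the last list was lost in 4 other settings, with percentiles from 95.035 to 97.48.

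The targets of the drug were not among the genes past the rule in cultured cells. Of 9 measured Src family and Abl kinase genes, counting CSK, 0 passed: SRC was at 0.17 ± 0.18, YES1 at -0.36 ± 0.04, FYN at -0.24 ± 0.11, LYN at 0.31 ± 0.03, LCK at -0.15 ± 0.09, FRK at 0.72 ± 0.92, ABL1 at 0.18 ± 0.32, ABL2 at -0.62 ± 0.14 and CSK at -0.17 ± 0.30. The list's median of -0.15 was at percentile 9.19. The medians of p53 targets (0.10), the unfolded protein response (0.13), NRF2 targets (0.16), STAT3 targets (0.06) and invasion proteases (0.08) lay inside the random range. So did those of biliary epithelium (0.12), keratinocyte-like differentiation (0.08), heat shock (-0.02) and oxidative phosphorylation (0.08). That of ribosomal proteins did too (0.03), though it was 0.37 and -0.40 on the single arrays. Genes of these lists past the rule in cells were AKR1C1 and AKR1C3 (1.41 ± 0.05), BCL6 (1.14 ± 0.21), MMP7 (1.69 ± 0.07), MMP10 (1.39 ± 0.21, with untreated cells above background on 1 of the 2 arrays), TIMP3 (-1.70 ± 0.15), TFF3 (1.45 ± 0.22), MUC1 (1.23 ± 0.21), KRT13 (-1.12 ± 0.11) and SPRR3 (1.005 ± 0.35).

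Some genes in cultured cells were well above background in 1 group alone and have a bound. MSMB was at least 3.90-fold higher after treatment, KCNE3 at least 3.40-fold and ATP10B at least 2.58-fold. MAP7D3 was at least 5.26-fold lower, the BMP antagonist gene NOG at least 2.49-fold and WNT11 at least 2.23-fold. The counts in cells depended on scaling: with median centring in place of loess, 30.3% of the genes past the rule were higher, against 52.3%. Without cultured cells replicate 2, 321 genes fell, against 190, by a rule on 1 array in which dye bias stays.

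In xenografts after saracatinib, the NF-kB and chemokine list had the highest median, with 5 of 19 genes past the rule. The keratinocyte-like list had the lowest, and 9 of its 18 genes fell. The chemokine gene CCL20 (chromosome 2, 228681100 to 228681836) rose by 3.23 ± 0.31 log2, or 9.37-fold. FCGBP rose by 3.08 ± 0.22, the immunoglobulin transporter gene PIGR by 2.86 ± 0.23 and the MHC class II gene HLA-DRA (chromosome 6, 32412448 to 32412507) by 2.82 ± 0.05. The stromelysin gene MMP10 (chromosome 11, 102641405 to 102641464) fell by 3.41 ± 0.03, or 10.6-fold, and KRT5, a basal keratin (chromosome 12, 52908622 to 52908681), by 2.66 ± 0.31. In all, 131 of 21107 tested genes rose and 106 fell, against 15 genes with unturned arrays.

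The rest of the 12 highest in xenografts were VNN2 (2.82 ± 0.06), HLA-DRB5 (2.67 ± 0.06), the NADPH oxidase gene NOX1 (2.37 ± 0.17 on its brightest probe and 0.53 on its weakest), LCN2 (2.27 ± 0.22), the acute phase genes SAA1 (2.26 ± 0.37), SAA2 (2.07 ± 0.15) and SAA4 (2.13 ± 0.07), and UBD (2.20 ± 0.07). The lowest RefSeq-named gene was the U3 small nucleolar RNA gene SNORD3B-1 at -5.37 ± 0.65, with both of its probes below -5. It was followed by MMP10, the desmosomal cadherin gene DSG3 (-2.91 ± 0.07), KRT5, the collagenase gene MMP1 (-2.40 ± 0.19) and LGALS7 (-2.36 ± 0.68). KRT6A (-2.32 ± 0.13), KLK5 (-2.14 ± 0.14), the matrix gene TNC (-1.95 ± 0.24), SNAI2 (-1.92 ± 0.19), VAV3 (-1.86 ± 0.18) and the glucose transporter gene SLC2A3 (-1.82 ± 0.17) completed the lowest 12.

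The keratinocyte-like list had the lowest median in xenografts, at -0.97 (percentile 0). Of its 18 measured genes 9 fell, led by KRT5, KRT6A and SPRR1B (-1.74 ± 0.05), and 2 rose, LCN2 and PI3 (1.52 ± 0.20). Of 16 invasion protease genes, MMP10, MMP1, MMP3 (at least 2.31-fold) and PLAU (-1.32 ± 0.17) fell and MMP7 rose (1.53 ± 0.15), with a median of -0.62 (percentile 0). PI3 and PLAU lie outside the rule for naming genes and were named after their values were seen. In the same RNA pair the fibroblast markers had a median of -0.10 (percentile 4.08) over 13 measured genes, with DCN at 1.55 ± 0.06 on its brightest probe and 0.48 on another.

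Cholesterol synthesis genes lay lower in treated xenografts, with a median of -0.61 (percentile 0) and 1 of 24 genes above 0. Genes that fell included MSMO1 (-1.10 ± 0.51) and squalene epoxidase, SQLE (-1.04 ± 0.18). Fatty acid synthesis genes had a median of -0.52 (percentile 0) over 10 genes, and SCD fell (-1.13 ± 0.05). Hypoxia and glycolysis genes had a median of -0.55 (percentile 0) over 19 genes, and ANGPTL4 (-1.42 ± 0.08) and NDRG1 (-1.25 ± 0.27) fell. Mitosis and G2/M genes had a median of -0.51 (percentile 0), with 0 of 28 above 0 and 0 past the rule. KIF20A (-0.74 ± 0.03) and the proliferation marker gene MKI67 (-0.71 ± 0.02 on its brightest probe and -1.502 on its lowest) had the largest values on the probes used. The 12 histone genes had a median of -0.34 (percentile 0.01), and 0 passed the rule.

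The NF-kB and chemokine list had a median of 0.74 (percentile 100), and all 19 measured genes lay above 0. Of these 5 rose, CCL20, BIRC3 (1.29 ± 0.26, named after its values were seen), CXCL1 (2.06 ± 0.19), CXCL3 (1.78 ± 0.23) and CXCL2 (1.48 ± 0.22). The macrophage and leukocyte markers measured beside it had a median of 0.11 (percentile 83.6) over 11 genes. The largest were CD14 (0.73 ± 0.02) and CD74 (0.73 ± 0.02). With both channels required above background, this marker list reached percentile 99.97.

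Smaller shifts in xenografts were those of YAP/TEAD targets (median -0.13, percentile 0.35), where F3 (-1.23 ± 0.29) and NT5E (-1.07 ± 0.29 on its brightest probe and -0.21 on another) fell among 23. Focal adhesion genes and Src substrates (-0.12, percentile 0.44) had 0 of 27 genes past the rule, with CAV1 at -0.91 ± 0.08 and ITGA5 at -0.77 ± 0.07. DNA replication genes (-0.09, percentile 1.28) had 0 of 30 past the rule, with TK1 at -0.54 ± 0.17 and CCNE1 at -0.35 ± 0.02. STAT3 targets had a median of -0.22 (percentile 0.22) over 10 genes with 0 past the rule. That call was lost without either array, at percentiles 14.3 and 6.25. The 8 endothelial markers had a median of -0.13 (percentile 1.70), with PECAM1 at 0.75 ± 0.02 and VWF at -0.34 ± 0.01, and the median was 0.05 without xenografts replicate 2.

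Several lists that were low in treated cells lay inside the random range in xenografts. These were the integrated stress response (-0.06, percentile 11.2), ERK output (-0.06, percentile 8.95) and immediate-early genes (-0.01, percentile 34.2), with 0 genes past the rule in each. Whether these lists differ between the systems was not tested. Src family and Abl kinase genes had a median of -0.13 (percentile 3.75) and 0 of 10 passed. Among them, SRC was at -0.33 ± 0.16, YES1 at -0.19 ± 0.03, FYN at 0.16 ± 0.09, LYN at 0.33 ± 0.04, LCK at -0.15 ± 0.10, FRK at 0.38 ± 0.13, ABL1 at -0.11 ± 0.27, ABL2 at -0.15 ± 0.14 and CSK at -0.14 ± 0.19.

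Also inside the random range in xenografts were interferon response (0.03, with CXCL10 up at 1.45 ± 0.10), lysosome and autophagy (-0.04), the unfolded protein response (0.08), p53 targets (-0.07), aryl hydrocarbon receptor targets (0.03) and heat shock (-0.13). NRF2 targets were at -0.05 and HMOX1 fell (-1.22 ± 0.28). Epithelial identity was at 0.04, mesenchymal identity at 0.04 with SNAI2 past the rule, and biliary epithelium at -0.01 with the mucin gene MUC5AC lower (-1.13 ± 0.30). Ribosomal proteins (0.10), oxidative phosphorylation (0.04), erythroid markers (0.07) and skeletal muscle and fat markers (-0.09) completed the lists. On the single arrays ribosomal proteins were at 0.38 and -0.15. In cultured cells, fibroblast (0.14), endothelial (-0.04) and macrophage and leukocyte markers (0.06) lay inside the range as well. Of the muscle and fat markers 3 were measured there (median 0.82, percentile 99.7), and the call was lost with no filter on dim probes (percentile 76.7). Fewer than 3 erythroid markers were measured in cultured cells, so that list has no median there.

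Genes measured in 1 group of xenografts alone were UBASH3A, at least 3.49-fold higher after treatment, HLA-DMB, at least 3.43-fold higher, and CA8, at least 2.48-fold higher. Besides MMP3, CLIC6 was at least 2.08-fold lower and GPR158 at least 1.91-fold. Without xenografts replicate 1, 295 genes rose, against 131 with both arrays, by a rule on 1 array in which dye bias stays.

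**Figure D1:**
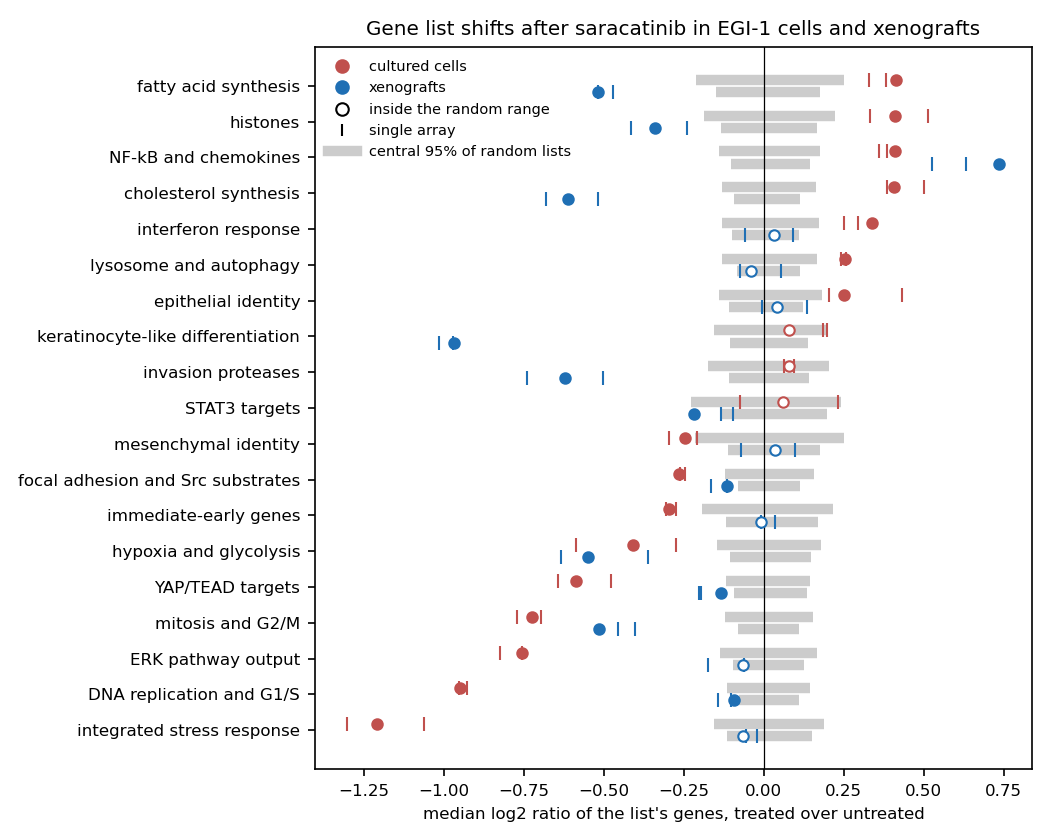
Median log2 ratio (treated over untreated, x axis) of gene lists called in at least 1 system, for cultured cells and xenografts, with ticks for the single arrays and grey bars for the central 95% of random lists. The integrated stress response lay at -1.21 in cultured cells and -0.06 in xenografts, and cholesterol synthesis at 0.41 and -0.61. The endothelial, muscle and fat, and aryl hydrocarbon receptor lists are left out.

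Set against each other, the responses of cells and tumours overlapped mostly among genes that rose. Of 18069 genes tested in both systems, 35 rose in both, where independent lists would share 1.09. The 8 strongest RefSeq-named genes were UBD, FCGBP, the complement genes CFB (1.78 ± 0.10 in cells, 1.70 ± 0.18 in xenografts) and C3 (1.70 ± 0.04, 1.41), BNIP5, the matrix protease gene MMP7, CXCL10 and GPX2. UBD was at 2.001 in cells and 2.20 in xenografts and FCGBP at 1.98 and 3.08. Genes that fell in both were 4, where independent lists would share 0.841: ANGPTL4 (-1.60 and -1.42), the interleukin 7 receptor gene IL7R (-1.82 ± 0.03, -1.36 ± 0.09), KRT13 (-1.12, -1.24 ± 0.03) and the lymphangiogenic factor gene VEGFC (-1.33 ± 0.06, -1.04 ± 0.11).

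Genes that rose in cells and fell in xenografts were 5, against 0.932 expected of independent lists: MMP10 (1.39, on a probe dim in untreated cells, and -3.41), SCD (1.17 and -1.13), BTBD16 (1.06 ± 0.07, -1.68 ± 0.12), the myoglobin gene MB (1.05 ± 0.16, -1.27 ± 0.18) and SPRR3 (1.005 and -1.39 ± 0.23). None of the tested genes (0, against 0.982) fell in cells and rose in xenografts. Genes that rose in cells had a median of 0.42 in xenografts, with 72.9% above 0, and genes that fell in cells had a median of -0.17, with 25.7% above 0. Genes that rose in xenografts had a median of 0.80 in cells, and genes that fell in xenografts had a median of 0.04.

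Across genes, which are not independent replicates, the log2 ratios of the 2 systems correlated at r = 0.271 (Spearman rho = 0.249). Pairs of single arrays with the same dye orientation gave 0.394 and 0.400, and pairs with opposite orientation gave -0.0572 and 0.0994. The unturned means, which hold the dye effects, correlated at 0.783 between systems.

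With the 2 systems as the only independent RNA pairs, limma called 0 genes changed alike at an adjusted p under 0.05. The smallest adjusted p was 0.328, and 1882 genes had an unadjusted p under 0.05. UBD, at 2.001 in cells and 2.20 in xenografts, was not called either, so 0 calls do not show that no gene changed alike. There were 2 RNA pairs, which also differ in dose, time and setting. With 1 array left out, so that dye bias stays in that system, limma called up to 20 genes. For each of the 33 lists the count over all genes was 0. Adjusted over the list alone, it was 24 of 28 for mitosis and G2/M, 8 of 19 for NF-kB and chemokines, 7 of 19 for hypoxia and glycolysis, 5 of 9 for STAT3 targets, 4 of 14 for invasion proteases and 4 of 16 for keratinocyte-like differentiation. It was 3 of 23 for YAP/TEAD targets, 2 of 9 for mesenchymal identity, 2 of 15 for NRF2 targets, 1 each for focal adhesion, interferon response and aryl hydrocarbon receptor targets, and 0 for every other list. The counts within lists were not adjusted across the 33 lists and carry no direction. Genes of a list also rest on the same 2 RNA pairs and are not separate findings.

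**Figure D2:**
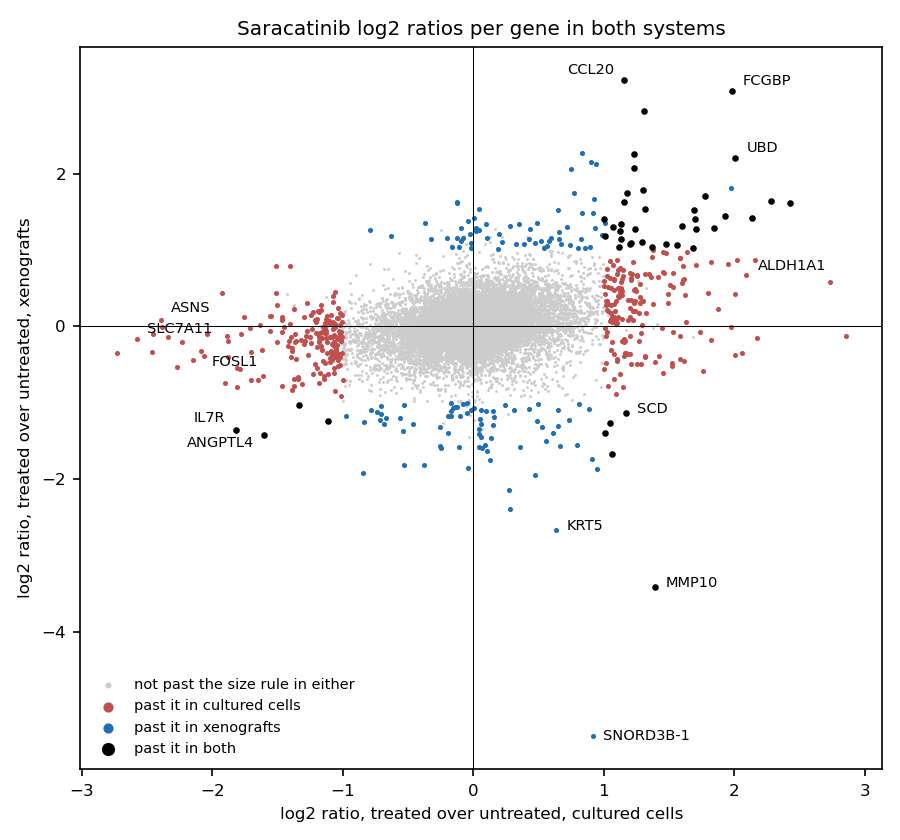
Mean log2 ratio of treated over untreated per gene in cultured cells (x axis) and xenografts (y axis), for the 18069 genes tested in both, coloured by whether they passed the size rule. The 35 genes that rose in both lie at the upper right, with UBD at 2.001 and 2.20, and MMP10 lies at the lower right at 1.39 and -3.41.

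**Figure D3:**
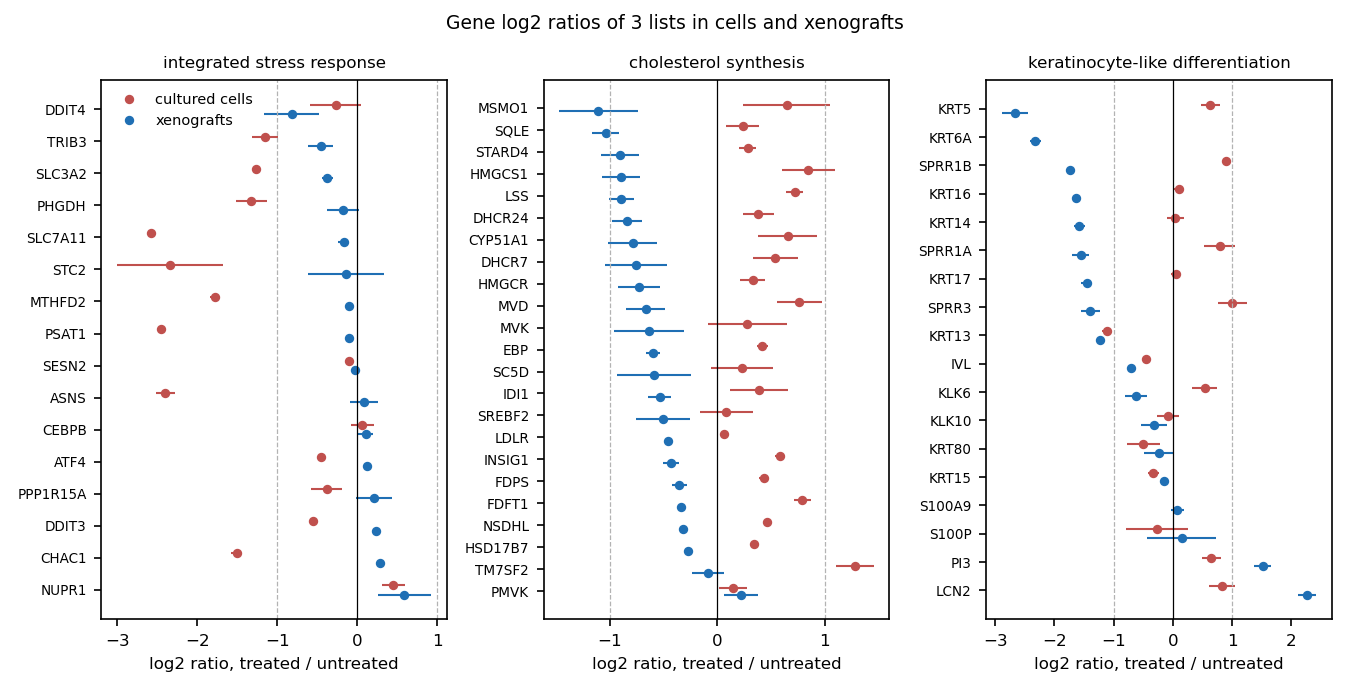
Log2 ratio of treated over untreated (x axis) for all but 1 of the measured genes of the integrated stress response, cholesterol synthesis and keratinocyte-like lists in cultured cells and xenografts, with a point for the mean, a bar spanning the 2 arrays and dashed lines at the 2-fold threshold. The median of all measured cholesterol synthesis genes was 0.41 in cells and -0.61 in xenografts.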

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

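The checks of dye bias and scaling for the lipid genes, and of dye bias and fibroblast markers for the keratinocyte-like genes, were chosen after the results they measure were seen. The patterns themselves were noticed in the data.

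Some results moved one way on both arrays of cultured cells and the opposite way on both arrays of xenografts, and these differences were not tested. Cells minus xenografts, the gap in log2 ratio was 4.80 for MMP10 (above background in untreated cells on 1 of the 2 arrays), 2.74 for BTBD16, 2.40 for SPRR3, 2.32 for MB and 2.30 for SCD. It was 1.02 for the median of cholesterol synthesis genes, 0.93 for fatty acid synthesis genes and 0.75 for histone genes.

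The 34 lipid synthesis genes had a median of 0.41 in cells and -0.59 in xenografts. Dye bias that is equal on both arrays cancels in the turned mean, so it could not have made these medians whatever its size. The unturned median, at most 0.0216 in size over the 2 systems, is therefore no test of it. If scaling alone made the direction, it would turn under another scaling. The smallest median in its own direction over 5 scalings was 0.22 (cultured cells, median centring), against 0.41 with loess. The sign was thus kept under each scaling, while the size in cells depended on it. With loess the SD of the medians on the 2 arrays was 0.06, and that with median centring was not computed. The systems also differ in dose, duration and setting, and those biological explanations remain untested.

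More genes rose in both systems (35) than independent lists would share (1.09), while dye effects correlated between systems. Shared dye bias that is equal on both arrays of a system cancels in the turned means that gave the 35 genes. It could thus not have made the overlap, and a check on single arrays is no test of it. At 1 log2 or more on single arrays with opposite dyes, 42 genes were shared against 3.24 expected and 37 against 1.60. The smaller ratio was 13.0. Among genes brighter than the median, 20 rose in both against 0.467 expected, a ratio of 42.8, which argues against dim probes. A response shared by cells and tumours may account for the overlap, as a hypothesis that 1 RNA pair per system cannot test.

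The keratinocyte-like list fell in treated xenografts, and the 9 genes that fell were a median of 5.80 log2 higher in untreated xenografts than in untreated cells. Dye bias that is equal on both arrays cancels in the turned mean, so the unturned median of 0.0503 is no test of it. A fall of fibroblast stroma as large as that of the 9 genes (at most -1.24) is argued against by 7 fibroblast markers. These were the markers not measured in cultured cells, with a median of 0.11 (from -0.35 to 1.55). Over all 13 measured markers the median was -0.10 (percentile 4.08), so a small fall is not excluded. Those markers do not cover other host cells, and the probes were not matched to mouse transcripts. Mouse skin around the untreated tumour cannot be told apart from a change in the tumour cells: 7 of 20 cornified layer genes were measured (median -0.0796, 2 lower), but 5 of the 7 were also measured in cultured cells, so their own expression could hide skin. The bound set before this test was met by the median, and the reading was tightened after the result was seen because of that overlap.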

How the results depend on the processing

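All settings here were planned before the data were examined. Several counts moved, while 0 genes past the rule in the main setting were past it in the opposite direction under another setting of the size rule. With Agilent's own log ratio, 415 genes rose and 426 fell in cultured cells, 324 rose and 241 fell in xenografts, 68 rose in both and 19 fell in both, and all 398 and 237 genes of the main setting were among them. With an offset of 0, 317 genes rose in cells, 217 rose in xenografts and 10 fell in both. With median centring, 130 rose and 299 fell in cells (30.3% higher, against 52.3%), and 298 of the 398 genes remained. At 1.5-fold the counts were 716 and 734 in cells, 437 and 348 in xenografts, and 129 and 63 in both, and at 3-fold 42 and 35, 31 and 23, and 5 and 0. These last moves follow from the threshold, and the cause of the others was not tested. With limma on the 4 arrays as if they were separate replicates, which measures technical spread, 4606 rose and 4076 fell in cells and 3741 rose and 3267 fell in xenografts.

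Leaving out each array in turn gave 263 to 278 genes higher and 199 to 321 lower in cells, 147 to 295 higher and 135 to 146 lower in xenografts, 35 to 39 higher and 3 to 6 lower in both, 0 to 20 changed over both systems, correlations of 0.182 to 0.306 and 30 to 32 list shifts, against 31. The median of endothelial markers in xenografts ran from -0.147 to 0.0454 with each array left out (-0.13 with both), turning above 0 without xenografts replicate 2, and the cause was not tested. No background subtraction, the authors' matrix (379 of 398 and 225 of 237 genes shared), both channels required, all probes of a gene, no condition on single arrays, unmatched random lists and another prior kept each count within 1.5 times. Dropping the filter on dim probes changed no count of genes past the rule. Among single genes and list medians, 113 moved by over 1 SD with Agilent's log ratio, 130 with median centring, 84 with an offset of 0, 38 with all probes and 29 with the authors' matrix. A slide or scan block was not run, since there was 1 slide and 1 scan. No paired analysis was possible because within a system the results come from no test. Signal over background limits the ratios of dim genes.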

Other observations

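The untreated RNAs of the 2 systems differed in many of the gene groups that also differed between treated and untreated cultured cells. This comparison and the lists of antigen presentation, mucosal defence, desmosome and small RNA genes were chosen after the data were seen, and with 1 RNA per group none has a test. Between untreated xenografts and untreated cells, 1179 of 13936 protein-coding genes were at least 1 log2 higher in xenografts and 812 at least 1 log2 lower. Lower in xenografts were the medians of the integrated stress response (-1.19), NF-kB and chemokines (-1.01), YAP/TEAD targets (-0.95), mitosis (-0.92), DNA replication (-0.57) and ERK output (-0.50), each at percentile 0.05 or below. After treatment of both, the difference was -0.09 for the integrated stress response, 0.44 for DNA replication, 0.11 for ERK output, -0.35 for NF-kB and chemokines, -0.58 for YAP/TEAD targets and -0.58 for mitosis. The untreated culture is 1 RNA and enters both the drug comparison in cells and this one, so they share its chance values.

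Higher in untreated xenografts were keratinocyte-like genes (median 2.36, 11 of 18 at least 1 log2 higher), histones (1.56), immediate-early genes (1.23), interferon response (1.20), biliary epithelium (1.10) and mesenchymal identity (1.10), each at percentile 100. KRT5 was 8.19 log2 higher and KRT17 7.69. Of 13 fibroblast markers 9 were at least 1 log2 higher, most of them on probes near background in untreated cells, so the size of their difference is open. Where a gene was near background in 1 of the RNAs, the difference is a lower limit. Xenograft RNA may also hold mouse host RNA read by the human probes, so no difference between the systems can be assigned to the tumour cells alone. Of 4 erythroid markers 1 was at least 1 log2 higher in untreated xenografts and 0 lower. Of 11 macrophage and leukocyte markers these counts were 3 and 0. Cholesterol synthesis genes were lower by a median of -0.73, and by -1.90 between the treated RNAs.

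Of 14 MHC class II genes measured in xenografts, 7 rose after treatment, 7 did not pass the rule and 0 fell, with a median of 1.02 (percentile 100). The probes of the related HLA-DRB genes were not checked for cross-hybridization, so the 7 may not be separate genes. Besides HLA-DRA, HLA-DRB5 and HLA-DMB, those that rose were HLA-DRB4 (above background on 1 of the 2 arrays without treatment), HLA-DRB3 at 1.42, HLA-DPA1 at 1.27 and HLA-DMA at 1.19. The class II regulator CIITA was at 0.85. In cultured cells 7 of the class II genes were measured, with a median of 0.14 (percentile 82.7), and HLA-DMA rose (1.01). MHC class I genes had medians of 0.40 in cells (percentile 99.9) and 0.33 in xenografts (percentile 99.97), with 0 past the rule in either. On the single arrays the class I medians were 0.52 and 0.21 in cells and 0.55 and 0.06 in xenografts.

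A list of acute phase and mucosal defence genes was drawn in part from the highest genes, so its counts are no test. Of its genes 7 of 12 rose in cells and 13 of 18 in xenografts, where DUOX1 fell (-1.51). Desmosome and hemidesmosome genes had medians of -0.24 in cells (percentile 0.91) and -0.33 in xenografts (percentile 0), and DSG3 was the 1 gene of 14 that fell in xenografts. Cornified layer genes had a median of 0.10 over 5 genes in cells.

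The fall of SNORD3B-1 in xenografts stood alone among small RNAs. Without it, the small nuclear, nucleolar and related RNAs measured in xenografts ran from -0.67 to 1.34, with a median of -0.16. RNU2-1 rose (1.34). In cultured cells SNORD3B-1 was at 0.91 and 0 of 30 small RNAs passed the rule.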
